A study of Microtus ochrogaster with 6 samples.

How the data were processed

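RNA from the nucleus accumbens of prairie voles was extracted with a combined nucleic acid kit and made into 6 directional poly(A) libraries, per the labels' protocols. Trim Galore, kallisto, StringTie and DESeq2 are named in the submitters' processing notes, without versions, and the part each tool played is not given in the sources used here. The genome build is also not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and columns were matched to samples by the library names in the labels.

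The deposited gene table holds whole-number counts per Ensembl gene identifier for 19648 genes, with totals of 17652854 to 27786606 per library, and 1899 genes have no count in any library. Whether the authors counted reads directly or rounded estimated counts is not given in the sources used here, nor is whether counting used strand. The deposited isoform table, although named as counts, holds a signal of another kind. Every value above 0 in a library (100%, within a tolerance of 0.01 steps) is a whole multiple of one constant for that library, between 8.80e-05 and 1.44e-04, the same for all isoforms. An abundance given to a fixed number of decimals and multiplied by a library factor has this form. The values are therefore not numbers of reads per isoform, though they may rise with them. Both tables give identifiers only: 0 of 19648 gene identifiers matched a symbol in the reference table used, and the 40 gene lists fixed beforehand, among them cell type markers, dopamine and oxytocin signalling and DNA methylation genes, could therefore not be tested. Contamination by neighbouring tissue, blood or other cell types and the sex of the animals were not checked for the same reason.

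Gene counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM, and fitted with robust quasi-likelihood models with maternal treatment as the single factor over all 6 libraries, which leaves 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Standard errors were taken as the absolute log2 difference divided by the square root of the F statistic, and 95% intervals used the moderated degrees of freedom.

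The same count model had been planned for isoforms, with an edgeR test of usage. Because the isoform values are not counts, log2 values per 1000000 (ppm) of the TMM-scaled library total, with a prior of 2 units, were tested instead with limma 3.58.1 (moderated test with trend and robust variances), after the same filter on rounded values. The prior of 2 units, fixed beforehand for log2 values of genes, was kept for isoforms after the numbers of calls at priors of 0.1, 0.5 and 2 had been seen, and of these it gave the most calls. Isoform usage was tested on the log2 ratio of an isoform to the other assembled isoforms of its locus, with 0.1 ppm added to each, and the isoform p-values of a locus were combined by Simes' method. This test took the place of the edgeR test of usage first planned. Limma's diffSplice had also been set aside, before it or this test was counted on the real values. The reason was false calls in simulated data, whose values are not given here. Loci were read from the assembled isoforms' identifiers, so isoforms with Ensembl identifiers entered no locus. The uncertainty of assigning reads to isoforms is not in the values and enters none of these tests.

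Each test was tested on simulated data with 200 changed features. In the gene simulation, over 14500 genes, 10 unchanged genes were called. In the isoform simulation, over 44910 isoforms, 3 unchanged isoforms were called, and the test recovered 0% of 1.5-fold, 2.94% of 2-fold, 18.2% of 4-fold, 30.3% of 16-fold, 60.6% of 64-fold and 54.5% of 1024-fold changes. In the usage simulation, over 4847 loci, 0 unchanged loci were called, and 0% of changes of 1.5-fold to 16-fold, 12.1% of 64-fold and 33.3% of 1024-fold changes in the odds were recovered. All draws were independent between features, with normal values for isoforms and usage. The calls on unchanged features therefore do not show how many false calls the real values give. On the real values, divisions of the libraries other than by treatment called 35 to 90 isoforms and 2 to 46 loci. The larger sizes were added after simulations of smaller ones had recovered few or no changes. The median SD of log2 values within a group was 0.20 for genes and 0.61 for isoforms. All pairs of libraries differed by more than sampling noise, with chi-square per degree of freedom of at least 17.65 over the tested genes, so none was treated as a duplicate.

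Identifiers named in the text follow a rule fixed before the data were examined, which asked for gene symbols and more genes per direction and was shortened because no identifier was paired with a symbol: the 2 higher and 2 lower genes with the smallest p among those with a mean log2 CPM of at least 1 and no overlap between groups, the 2 higher and 2 lower isoforms with the smallest p, and the 2 loci with the smallest p. The rule also names oxytocin, vasopressin and their receptors, for which no values are given for the same reason. Alternatives were other size factors, other filters, DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, leaving out each library, the edgeR test first planned for isoforms and, chosen after seeing the data, a term for library order, other priors and pseudocounts, and isoforms above 0 in all 6 libraries. DESeq2 and voom were run on rounded isoform values for comparison.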

Results

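Poly(A) RNA from the nucleus accumbens, a ventral striatal region involved in reward and social behaviour, was sequenced in 6 libraries from prairie voles (Microtus ochrogaster). The prairie vole is a socially monogamous rodent in which oxytocin, a peptide hormone of birth, lactation and social bonding, has been studied widely. In 3 libraries the tissue came from offspring of mothers injected with oxytocin before birth, and in the other 3 from offspring of mothers injected with saline. The comparison asks how exposure to exogenous oxytocin around birth relates to gene expression in the juvenile brain. The labels do not say whether the libraries of a group came from separate animals or litters, so the p-values measure only the spread between these libraries, which may in part be technical. The gene table held 18558975, 26577388 and 24466666 counts in oxytocin replicates 1, 2 and 3, and 27786606, 17652854 and 26246220 counts in saline replicates 1, 2 and 3. Between 16236 and 16629 genes had at least 1 count per library. Genes and isoforms are given by identifier, because the tables used here do not pair these identifiers with gene names or positions.

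No gene passed edgeR's test between the offspring of oxytocin-treated and saline-treated mothers. Of 19648 genes in the table, 14500 had enough counts to be tested, and 0 were higher and 0 lower in the oxytocin libraries by edgeR's quasi-likelihood test at an adjusted p of 0.05. The smallest adjusted p rounded to 1. At an unadjusted p under 0.05 there were 235 genes, 131 with higher and 104 with lower means in the oxytocin libraries, where 725 would be expected by chance. DESeq2, run without the filter on low counts over 17720 genes, called 5, 2 higher and 3 lower. Limma voom with quality weights called 0 of the 14500. In 834 genes, 5.75% of those tested, the 3 oxytocin libraries lay entirely above or entirely below the 3 saline libraries, against the 10% that chance gives.

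The precision of the gene comparison differed with abundance. Among the 5921 genes with a mean of 32 CPM (TMM-scaled counts per 1000000) or more, the median absolute log2 difference between groups was 0.06, and none differed by more than 2-fold. The pointwise 95% interval of the difference lay within 2-fold in either direction for 5850 of these genes (98.8%) and within 1.5-fold for 5346 (90.3%). Among the 6917 genes with a mean of 2 to 32 CPM, the interval lay within 2-fold for 84.9%. Among the 1662 genes below 2 CPM it did so for 16.2%, so for most of these genes a 2-fold difference was not excluded. In simulated counts with the means and dispersions of these 14500 genes, the same test recovered 87.9% of 4-fold changes, 53.7% of 2-fold changes and 16.4% of 1.5-fold changes. The simulation drew each gene independently and changed 200 genes at once. The real comparison gave fewer small p-values than chance, so these shares may overstate what it could detect.

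The 2 higher and 2 lower genes with the smallest p-values, among those averaging at least 2 CPM and separating the groups, are given as values, since none passed edgeR's test. ENSMOCG00000016859 stood at 6.97 ± 2.13 CPM in the oxytocin libraries and 2.46 ± 0.34 CPM in the saline libraries (SD, n = 3 each), a fitted ratio of 2.82-fold with an SE of 0.28 on the log2 scale. ENSMOCG00000007124 stood at 12.2 ± 7.05 and 2.70 ± 1.03 CPM (SD, n = 3 each), a ratio of 4.52-fold with an SE of 0.46 on the log2 scale. ENSMOCG00000014373 stood at 0.78 ± 0.18 CPM in the oxytocin libraries and 5.08 ± 2.25 CPM in the saline libraries (SD, n = 3 each), 6.41-fold lower with an SE of 0.42 on the log2 scale. ENSMOCG00000002320 stood at 0.55 ± 0.43 and 3.75 ± 0.52 CPM (SD, n = 3 each), 7.04-fold lower with an SE of 0.51 on the log2 scale; its log2 difference of -2.82 became -3.59 without oxytocin replicate 1. In each of the 4 genes all 3 oxytocin libraries lay on one side of all 3 saline libraries, which was a condition for naming them. These 4 genes were among the 5 that DESeq2 called, with DESeq2 adjusted p of 0.0187, 0.00329, 8.45e-05 and 0.000513 in that order. Over the 14 alternatives of each gene the adjusted p (edgeR, limma or DESeq2) ranged from that DESeq2 value to 1, and DESeq2 was the single alternative past the threshold. The remaining DESeq2 call, which was examined after its values were seen, had 0 or 1 count in 4 libraries and 424 and 535 counts in saline replicates 2 and 3. It did not pass the filter of the edgeR test.

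**Figure D1:**
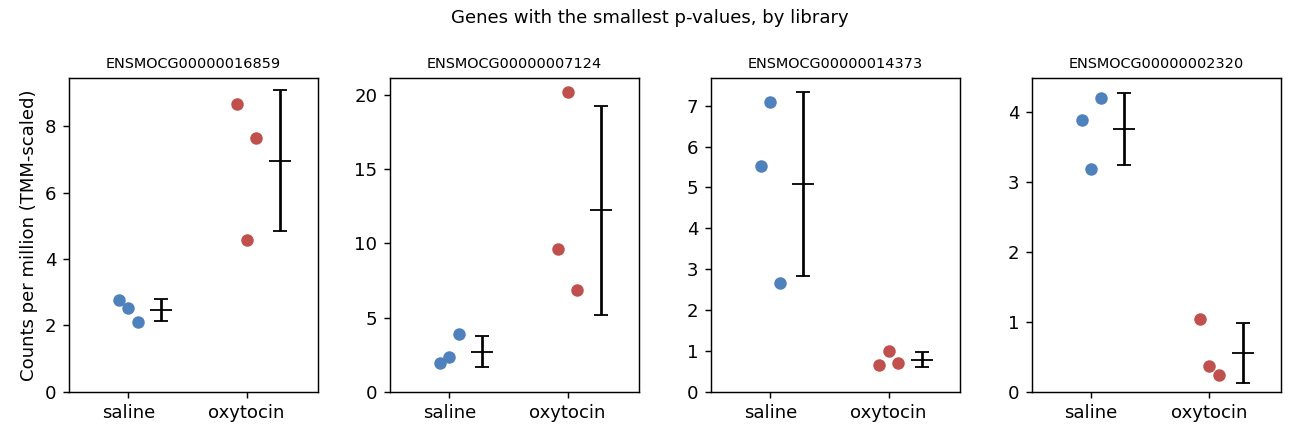
Expression of the 4 named genes, in TMM-scaled CPM on linear axes that start at 0. Each point is a library, and the horizontal mark and bar are the mean and SD of 3 libraries. The saline and oxytocin points do not overlap in any panel because the genes were chosen for this, and no gene passed edgeR's test.

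Whole gene profiles did not separate the groups. Maternal treatment accounted for 15% of the variance of log2 CPM over the 14500 genes, where 20% would be expected with no difference between groups, and 8 of the 10 ways of dividing the 6 libraries into 3 and 3 gave at least as much (exact permutation p = 0.8, one-sided, with 0.1 the smallest p this design allows). Spearman correlations across genes ranged from 0.980 to 0.990 for the 6 pairs of libraries within a group and from 0.980 to 0.991 for the 9 pairs between groups. The first principal component held 36.9% of the variance, and its extremes were saline replicate 3 at 41.4 and oxytocin replicate 2 at -29.6, with saline replicate 1 also at -29.6. The 10 most abundant genes took 9.73% ± 1.73 of counts in the oxytocin libraries and 9.31% ± 1.99 in the saline libraries (SD, n = 3 each; exact permutation p = 0.9, two-sided).

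**Figure D2:**
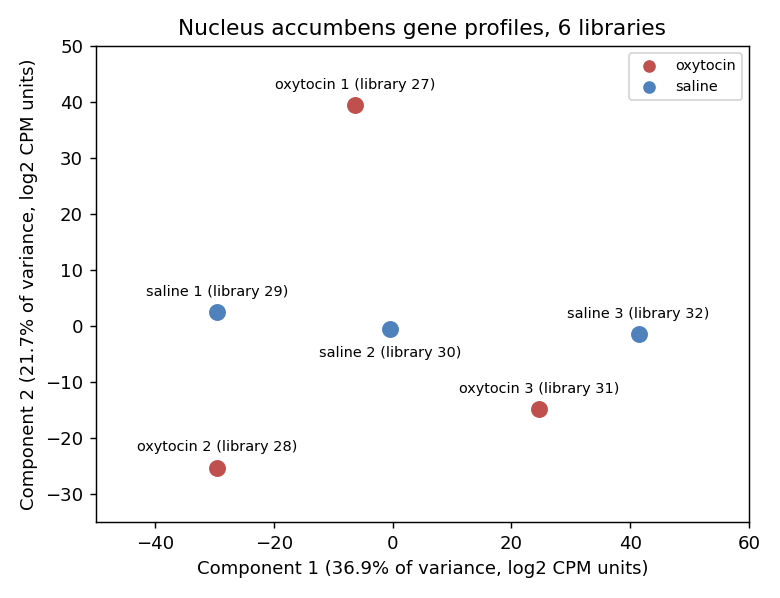
First and second principal components of log2 CPM over the 14500 tested genes, with the share of variance on each axis. Each point is a library, coloured by maternal treatment and marked with its library number; saline libraries lie near both ends of the first component.

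The isoform table lists 69383 isoforms, 31519 with Ensembl transcript identifiers and 37864 assembled ones, and its values are scaled abundances rather than read counts. Of 44910 tested isoforms, 57 passed limma's test at an adjusted p of 0.05, and 22 rose and 35 fell in the oxytocin libraries. Of the 10 ways of dividing the libraries into equal groups, 7 gave at least 57 calls, the treatment groups included. The highest other count was 90, so the number of calls does not set the treatment groups apart from other divisions. All 57 separated the groups completely, which follows largely from their being called with 3 libraries per group and is no further support. In 9 of the 57 the value was listed at 0 in every saline library and above 0 in every oxytocin library, and in 21 the reverse held. Called or not, isoforms with either pattern numbered 165, and the other divisions gave 110 to 168. Of the 23 called isoforms above 0 in all 6 libraries, 22 differed by more than 8-fold on the log2 scale with a prior of 2 units, with a median absolute log2 difference of 4.96. Assembled isoforms made up 50 of the 57 (87.7%) and 62.8% of those tested (Fisher's exact test over isoforms, which are not independent, two-sided p = 4.64e-05). At an unadjusted p under 0.05 there were 1571 isoforms, with 2246 expected by chance.

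Among the isoforms that rose, MSTRG.12078.1 was listed at 0 in all 3 saline libraries and at 386.8, 257 and 249 ppm (units per 1000000 of the TMM-scaled library total) in oxytocin replicates 1, 2 and 3, with a limma adjusted p of 0.000435. MSTRG.1036.1 was listed at 0 in the saline libraries and at 69.3, 59.7 and 109.5 ppm in the oxytocin libraries, with a limma adjusted p of 0.00165. Among those that fell, MSTRG.17543.5 was listed at 0 in all 3 oxytocin libraries and at 125.4, 126.7 and 117.2 ppm in saline replicates 1, 2 and 3. MSTRG.16710.2 was likewise listed at 0 in the oxytocin libraries and at 101.4, 97.6 and 107.4 ppm in the saline libraries, both with limma adjusted p of 0.000435. Over 18 alternatives the adjusted p (limma, edgeR or DESeq2) ranged from 1.63e-38 to 0.999 for MSTRG.12078.1, from 8.41e-29 to 0.999 for MSTRG.1036.1, from 5.56e-34 to 0.186 for MSTRG.17543.5 and from 1.01e-32 to 0.213 for MSTRG.16710.2, with DESeq2 lowest and limma voom highest. EdgeR did not call the isoforms that rose (adjusted p 0.0616 and 0.112) and called those that fell (adjusted p 0.0281 for both), and limma voom called none of the 4. No fold is given against a group listed at 0, since a listed 0 can also be an estimate that failed, and the depth per isoform is unknown. The number of calls depended on the test and its settings: edgeR on the rounded values, planned as the main test before the values were found not to be counts, called 11, limma voom with quality weights 0, DESeq2 1082, limma with a prior of 0.1 units 26, limma with a mean of at least 1 ppm 33, and limma with a term for library order 8. With the replicate number as a block, limma called 0. The balance of directions turned with the library left out: without saline replicate 1, 2 or 3 there were 25, 19 and 24 higher and 7, 11 and 7 lower calls, and without oxytocin replicate 1, 2 or 3 there were 17, 13 and 7 higher and 48, 46 and 34 lower calls. Of the 57 isoforms, 12, 11 and 13 were called without saline replicate 1, 2 or 3, and 28, 27 and 24 without oxytocin replicate 1, 2 or 3.

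An assembled isoform carries its locus number in its identifier, and 37 of the 50 called assembled isoforms lay in 32 loci with at least one other tested assembled isoform. Shares and totals of a locus cover its tested assembled isoforms alone. Isoforms with Ensembl identifiers entered no locus, and assembled isoforms held 36.49% to 37.13% of the isoform abundance of each library. The called isoform made up a median of 54.1% of its locus in the group where it was higher and 0.000168% in the other. For these 37 the summed abundance of the locus changed by a median absolute log2 of 0.21, and in 34 of the 37 by less than 2-fold. The median over all 15907 summed loci was 0.242. A called isoform that held less than the rest of its locus could not by itself change the total 2-fold. The count of 34 was therefore partly fixed in advance. Had the other isoforms stayed as they were, the median locus change would have been 0.97, and for 32 of the 37 the observed change was smaller than the change computed this way for that locus. Summed loci passed limma's test in 13 of 15907 cases, each a locus whose called isoform was its single tested assembled isoform. The sum in these loci is that isoform itself, so these calls repeat the isoform test.

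Isoform usage, the share of each isoform among the tested assembled isoforms of its locus, passed the test in 32 of 4847 loci by limma with Simes combination. At an unadjusted p under 0.05 by this test there were 253 loci, with 242 expected by chance. Of the 10 ways of dividing the 6 libraries into 3 and 3, 3 gave at least 32 loci, the treatment groups included. The highest other count was 46. MSTRG.16710 had 2 tested assembled isoforms. Of their summed abundance, MSTRG.16710.2 held 99.8% ± 0.14 in the saline libraries (SD, n = 3). It was listed at 0 in the oxytocin libraries, where the other of the 2 held 100%. The locus total was 66.3 ± 8.91 ppm in the oxytocin and 102.3 ± 4.91 ppm in the saline libraries (SD, n = 3 each), and the limma usage adjusted p was 0.00109. In MSTRG.17543, also with 2 tested isoforms, MSTRG.17543.5 held 34.7% ± 3.95 in the saline libraries (SD, n = 3) and was listed at 0 in the oxytocin libraries, with locus totals of 356.7 ± 28.3 ppm in the saline and 258.9 ± 26.8 ppm in the oxytocin libraries (SD, n = 3 each) and a limma usage adjusted p of 0.0039. The count of loci was 18 with no filter on low values, 17 with a mean of at least 1 ppm, 21 with a pseudocount of 1 ppm and 5 with a term for library order. It was 0 with the replicate number as a block. Without oxytocin replicate 1, 2 or 3 the test called 6, 18 and 12 loci, of which 4, 7 and 8 were among the 32, and without saline replicate 1, 2 or 3 it called 1, 11 and 1, of which 1, 4 and 1 were among the 32. In simulated data the usage test recovered 33.3% of 1024-fold, 12.1% of 64-fold and 0% of 16-fold or smaller changes in the odds, so most differences in usage would not have been detected.

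**Figure D3:**
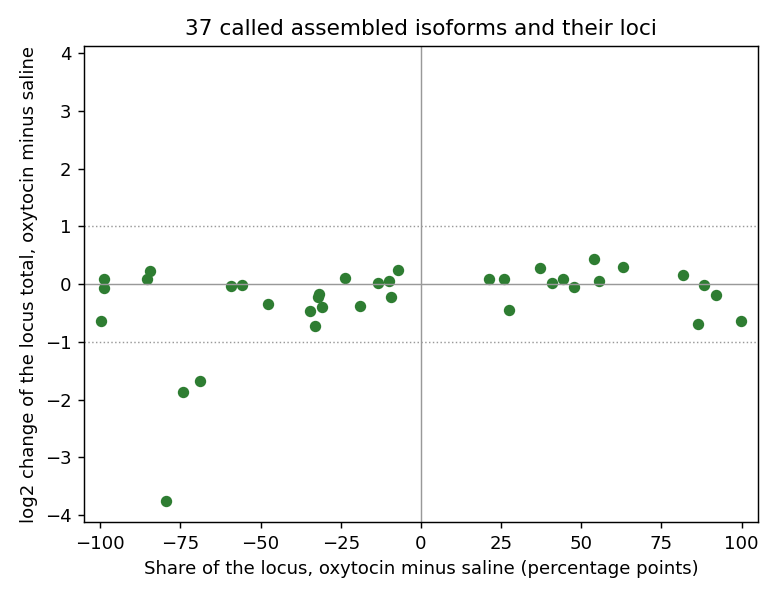
The 37 called assembled isoforms in loci with at least 2 tested assembled isoforms, with the change in their share of the locus (percentage points, oxytocin minus saline) on the horizontal axis and the log2 change of the locus total on the vertical axis. Each point is an isoform, and 34 lie between the dotted lines that mark a 2-fold change of the locus. Shares and totals cover tested assembled isoforms alone. An isoform that held less than the rest of its locus could not by itself move the total past these lines.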

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

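The library order term, the prior counts, the usage pseudocount and the restriction to isoforms above 0 in all 6 libraries were chosen after seeing the data; edgeR on isoforms was planned as the main test and became an alternative once the values were found not to be counts. The count of changed genes was 0 under both other scalings, both other filters, limma voom with quality weights and the library order term, and DESeq2 gave 5. Leaving out 1 library gave 0 to 1 genes: ENSMOCG00000001370, also the remaining DESeq2 call, was called without saline replicate 1, and ENSMOCG00000013417 without saline replicate 3, both lower in the oxytocin libraries and both named after their values were seen. The 57 changed isoforms became 33 with a mean of 1 ppm or more, 0 with limma voom and quality weights, 1082 with DESeq2, 11 with edgeR, 8 with the library order term (the 4 named isoforms among them, adjusted p 0.0108 to 0.0227), 26 with a prior of 0.1 and 24 among isoforms above 0 in all 6 libraries; other scalings, no filter and priors of 0.5 and 10 gave 44 to 73. Leaving out 1 library gave 30 to 65 isoforms, with more higher than lower calls without any 1 of the saline libraries and the reverse without any 1 of the oxytocin libraries. The 32 loci with changed usage became 18 with no filter, 17 with a mean of 1 ppm or more, 5 with the library order term and 21 with a pseudocount of 1 ppm; leaving out 1 library gave 1 to 18. For these changes in counts the cause was not tested. Same-numbered libraries deviated from their group means with correlations of 0.065, 0.0019 and 0.40 over genes, so the numbers were not taken to pair the animals. With the replicate number as a block, genes stayed at 0 and isoforms and loci went to 0; not every library correlated best with its own number. The share of variance between groups was 14.5% to 16.2% under other scalings and filters and 17.8% to 24.0% with 1 library left out, where 25% would be expected with no difference over 5 libraries. Over their alternatives the named genes kept their direction and their side of the threshold in 52 cases and passed it in 4, all DESeq2, and the named isoforms kept both in 62 cases and no longer passed in 10. No alternative of the gene list tests was run, because no identifier was paired with a symbol. Intervals were widest for genes below 2 CPM, with a median half-width of 1.07 on the log2 scale; what depth adds to this, beside the number of libraries and the spread between them, was not tested.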

Other observations

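Tests chosen only after the result was seen were the splits for genes and isoforms, the locus totals, the loci of isoforms listed at 0, the library number relation, the closest pair in depth, the span of the saline libraries, the mean over splits and, as a model term, library order. The closest pair and the span were added after earlier tests of depth and treatment on the same component had been seen.

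Isoforms that switched between nearly absent and abundant were found in many divisions of the 6 libraries. In 3169 of 44910 tested isoforms (7.06%) the sorted libraries were parted by a gap of at least 32-fold on the log2 scale with a prior of 2 units, against 15 of 14500 genes. Of these, 810 parted 3 libraries from 3, and 89 of the 810 parted the oxytocin from the saline libraries, where the other 9 divisions held between 61 and 96 each and the mean over all 10 was 81. Isoforms low in a single library were most frequent in the libraries of lowest depth, 301 in oxytocin replicate 1 and 294 in saline replicate 2, against 178 to 216 in the other 4. Isoforms listed at 0 in all of one group and above 0 in all of the other numbered 165, and 110 to 168 under the other divisions.

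The 57 isoform calls were weighed first. Of the 10 splits of the 6 libraries, 7 gave at least as many calls, and the highest other count was 90, in the split by library number; for usage the real value was 32 loci, the highest other 46, again by library number, with 3 of the 10 splits as large, and with 10 splits no share under 0.05 can be reached. Exact listed zeros are argued against as the source of every call, since 24 calls were made among isoforms above 0 in all 6 libraries. Some called isoforms of this kind still lay near the prior of 2 units in one group. MSTRG.4131.1, for example, was at 2.4, 4.7 and 1.5 units in oxytocin replicates 1, 2 and 3. A cut at exact 0 cannot tell such values from estimates that nearly failed. For 18 called isoforms listed at 0 in one group, in loci with other tested assembled isoforms, the locus change was set against loss of the isoform alone. The median ratio was 0.182 and the upper quartile 0.665, which argues against abundance simply dropped from the locus for most of them. It does not do so for each: the total of MSTRG.17543 was 356.7 ppm in the saline and 258.9 ppm in the oxytocin libraries. MSTRG.17543.5 itself held 123.1 ppm in the saline libraries, so a drop stays open there. For the 37 called assembled isoforms in loci with other tested ones, the locus totals changed by a median absolute log2 of 0.215. Had the other isoforms stayed as they were, it would have been 0.966, and over all summed loci the median was 0.242. The small change goes with abundance moving between the tested assembled isoforms of one locus. Such movement was not examined for 13 called isoforms that were the single tested one of their locus, where the total is that isoform itself. Nor was it examined for the 7 calls with Ensembl identifiers, which entered no locus. Movement to or from isoforms with Ensembl identifiers or below the filter is not seen in these totals. Whether movement within loci reflects splicing, sequence variants between animals or the assignment of reads to similar isoforms was not tested, and an effect of maternal treatment stays open.

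The first component of the gene profiles was weighed next. It went with library number, a candidate source that may stand for processing order, dissection or litter, though neither correlation passed an adjusted p of 0.05. Spearman's rho was 0.829 (exact permutation p = 0.0583, adjusted p = 0.175 over 3 relations) and Pearson's r 0.803 (exact permutation p = 0.0528, adjusted p = 0.158). Without the 2 libraries farthest from the median number r was 0.947, with no p computed, and so few libraries add no support. Depth gave rho -0.429 and r -0.075 (exact permutation p = 0.419 and 0.896, adjusted p = 0.628 and 0.896, r -0.656 without 2 libraries), and the share of the 10 most abundant genes rho -0.257 and r -0.091 (exact permutation p = 0.658 and 0.856, adjusted p = 0.658 and 0.896, r -0.087 without 2 libraries); both rho values lie under the bound of 0.5 set before they were seen, but 6 libraries leave weaker relations open. Against depth as the whole source, the pair closest in depth, saline replicate 3 and oxytocin replicate 2 at 26246220 and 26577388 counts, lay 100% of the component's range apart. Against maternal treatment as its main source, the saline libraries alone spanned 100% of the range to 3 digits, and the group difference had an exact permutation p of 0.7 where 0.1 is the smallest possible.

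The low number of small p-values in the gene test was weighed last. The real grouping gave 235 genes at an unadjusted p under 0.05, fewer than each of the other 9 splits (274 to 1779), and the 1779 came from the split by library number. Of the other splits, 1 that sets oxytocin replicate 1 and saline replicates 1 and 2 apart gave 1538 and 1 that sets oxytocin replicates 1 and 3 and saline replicate 3 apart gave 1222, which points to a structure of the samples that library number alone does not describe. Whether the test is too strict for these counts stays open: the mean over the 10 splits was 739 where 725 would be expected, but 7 of the splits lay below 725 and the median was 474.5, and splits that follow a structure of the samples raise the mean. With a term for the first against the last 3 library numbers the count was 310, so this coarse form of library order is argued against as the whole source, while a finer order or another factor shared across groups may contribute and stays untested. As for genes past the threshold, the real value was 0 and the highest other 1, 10 of the 10 splits gave at least as many, and 10 splits allow no share under 0.05.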
